A study of Mus musculus with 12 samples.

How the data were processed

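Ventricular RNA from mouse embryos at embryonic day 16.5 was measured on 12 single-colour expression arrays, 3 per genotype in 4 groups: wild type, Hdac2-null, Hopx-null and double-null, the last lacking both genes. Per the labels' protocols, total RNA was extracted with Trizol, reverse transcribed from a poly(T) primer that carried a T7 promoter, amplified linearly and labelled with biotin as cRNA. The labels call the replicates of each genotype biological replicates. No 2 arrays held identical values.

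The deposited table gives 1 intensity per probe set and array on a linear scale, for 45101 probe sets. The submitters' processing notes name MAS5, with no version. The deposited intensities had the shape of another kind of summary: 48.6% of all values lay within 1 unit of 4.5, none was below 3.6, and the upper quartile ranged only from 557.3 to 586 over the arrays. Values of this shape come from model-based, background-adjusted and quantile-normalised summaries returned to the linear scale, and the method behind the table is not given in the sources used here. The table was therefore used as deposited, with no further normalisation.

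Signals below a floor of 82.5, set at 0.1 times the mean of the arrays' 2% trimmed means, were raised to it before log2 transformation. Where the floor raised only arrays of the lower group, the log2 fold change understates the difference, and where it raised arrays of both groups it can shrink, enlarge or reverse it. A fold change is given as at least N-fold where every array of 1 group was at or below the floor and every array of the other above it. Platform annotation named 34945 probe sets with 1 gene, 932 with several and 9160 with none, and only the first kind was used, apart from 64 control probe sets used for RNA quality. Symbols were updated through gene identifiers against the reference gene table of assembly GRCm38.p6, which matched 34741 probe sets and was otherwise used only for the order of genes along chromosomes. Each of 18193 genes was represented by its probe set with the highest mean log2 signal. Of these, 12433 reached the 40th percentile of all probe sets (4.76 signal units), and 2766 of them were then left out because they were at the floor on all 12 arrays and had no variance. This last exclusion was decided after the values were seen, and left 9667 genes tested.

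Linear models with 1 coefficient per genotype were fitted over all 12 arrays with limma 3.58.1 in R 4.3.3, which gave 8 residual degrees of freedom. Moderated tests used an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method within each of 6 comparisons. A gene was called at an adjusted p under 0.05. Every adjusted p for a gene comes from limma. The comparisons were each null group against wild type, double-null against each single null, and the interaction of the 2 losses, which measures whether they add on the log2 scale.

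Gene lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01, in each null group against wild type and in the interaction. Camera with an estimated correlation and fry were run beside it. Of 37 lists, 33 had at least 3 tested genes. Lists of neural and Schwann cell, lung epithelium, thymus and fat markers had 2, 0, 0 and 1 tested genes and were not tested. Named genes followed a rule fixed before the data were examined: the 2 targeted genes and a set of cardiac and cell cycle genes always, the called genes or, where there were fewer than 5 in a direction, the 5 with the smallest p, and up to 4 members of each list that passed. Genes outside this rule are said to have been chosen after their values were seen.

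The fit was tested on simulated data for Hdac2-null against wild type, with 200 changed genes among 9667. It recovered 60.6% of 1.5-fold changes, 86% of 2-fold changes and 93% of 4-fold changes, and 6.23% of the calls were false. These shares depend on the 200 planted changes, since the Benjamini-Hochberg cut-off is stricter where fewer genes change. They do not carry over to the real comparison, where 2 genes were called, and do not show that changes of these sizes were absent. In 20 simulated runs per shift, camera called the sarcomere list in 100% when it was moved by 0.1 on the log2 scale and in 0% when it was not moved. In the same runs a mean of 0.3 other lists per run was called at a shift of 0.1, 1.1 at a shift of 0.2 and 0 without a shift. The noise was drawn independently for each gene, so these runs do not show how often camera calls an unmoved list of genes that vary together. In the measured data the estimated correlation ran from -0.137 for the sex-linked list to 0.929 for the liver list. The number of arrays, 3 per group, limits the precision, and the median SE of a log2 fold change was 0.11.

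The labels number the replicates 1 to 3 in each group. Same-numbered wild-type and Hopx-null arrays deviated together from their group means (r across genes of 0.42, 0.42 and 0.15), as did same-numbered Hdac2-null and Hopx-null arrays (0.21, 0.17 and 0.12). The numbers were therefore taken as a possible pairing of those groups. All arrays numbered 1 had a high Xist signal, and sex-linked genes were kept in these correlations. Shared sex was thus not separated from a pairing for the arrays numbered 1. Some arrays with different numbers also deviated together, such as wild type 3 and Hdac2-null 2 (0.50). The main fit was unpaired, and the numbers entered only an alternative fit, as a block. The possible pairing rests on the data, since the labels tie the numbers to no litter or day. The other 4 pairs of groups did not meet the criterion.

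Alternatives were no floor, quantile normalisation, median centring, no filter, all probe sets, no intensity trend, array weights, the replicate number as a block, only the groups compared, sex-linked genes left out and each array left out in turn. After the data were seen, 3 were added: log2 Xist signal as a covariate, a stricter filter at 2 floors (165 units), and a fit without wild type 1 and Hopx-null 1, the arrays at the low end of the first principal component. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.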

Results

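Gene expression in the cardiac ventricle was measured in mouse embryos at embryonic day 16.5, in 3 independent ventricles each of wild type, Hdac2-null, Hopx-null and double-null embryos. Hdac2 encodes a class I histone deacetylase, and Hopx a small homeodomain protein of the heart that does not bind DNA itself. The series addressed how deficiency of either gene, or of both, affects the embryonic heart. Signals ran from 3.6 to 57994 units, and between 37.51% and 37.89% of probe sets exceeded the floor of 82.5 units on each array. Correlations of log2 signal between arrays ranged from 0.978 to 0.995. The 3′ to 5′ signal ratios of beta-actin and Gapdh, measures of RNA integrity, were compared between each null group and wild type. All 6 exact two-sided permutation p-values were 0.3 or more (adjusted p = 0.8), where 3 arrays against 3 cannot give a p below 0.1. These tests of group means do not address single arrays. The Gapdh log2 ratio was 1.328 on wild type 1 and between 0.842 and 1.075 on all other arrays. The beta-actin log2 ratio of wild type 1, 2.756, lay within the range of the others (2.635 to 2.795). Xist, the transcript of the inactive X chromosome, was between 4988 and 6130 units on wild type 1 and 2 and on replicate 1 of each null group. It was at most 22.2 on the other 7 arrays, so the sexes were not balanced between the groups.

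The targeted genes followed the labels on every array. Hdac2 signal was 4839 ± 314 (SD, n = 3) in wild type and 4903 ± 679 in Hopx-null ventricles. It was 4.05 ± 0.0049 in Hdac2-null and 4.15 ± 0.148 in double-null ventricles, at least 58.6-fold below wild type (adjusted p = 1.01e-10 for each). Another Hdac2 probe set went from 2927 ± 145 in wild type to 4.72 ± 0.0616 in Hdac2-null ventricles, and a dim one from 33.6 ± 20.7 to 4.32 ± 0.0361. Hopx signal was 9817 ± 2080 in wild type, 1992 ± 111 in Hopx-null and 1700 ± 38.6 in double-null ventricles. A second Hopx probe set went from 787 ± 322 in wild type to 11.9 ± 1.94 in Hopx-null and 9.71 ± 0.0111 in double-null ventricles, below the floor. Where the probe sets lie relative to the deleted parts of the genes is not given in the sources used here, and a probe set outside a deleted part would not check the label.

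**Figure D1:**
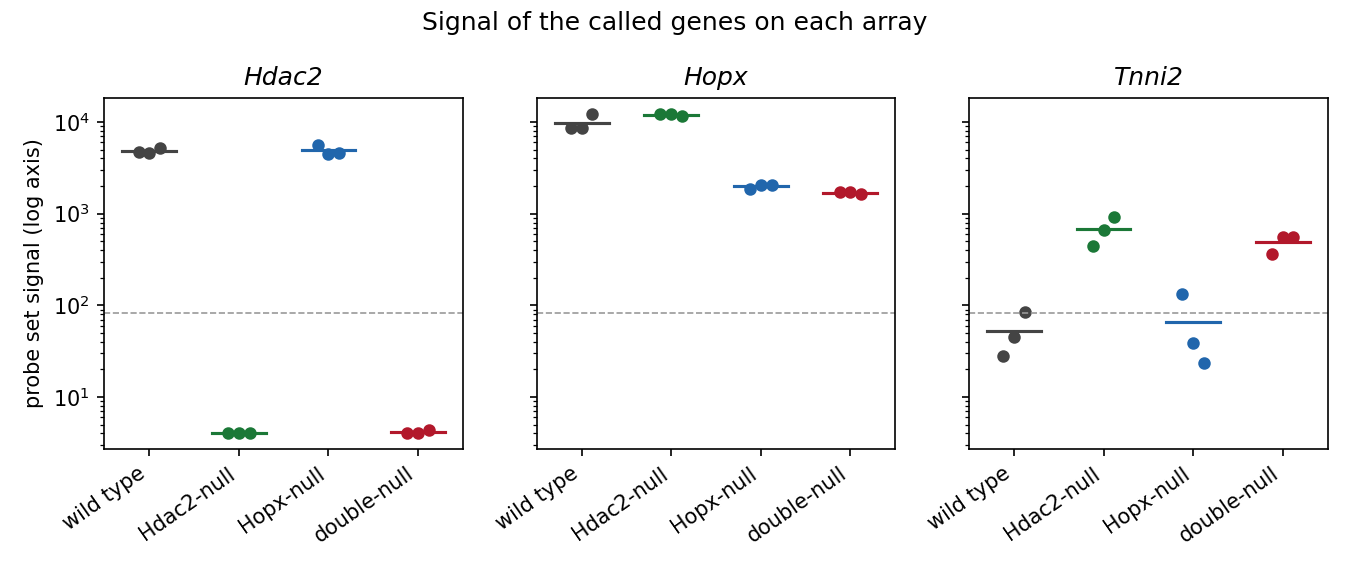
Probe set signal (log axis) of Hdac2, Hopx and Tnni2 on each of the 12 arrays by genotype; points are arrays, horizontal bars are means of 3 arrays and the dashed line is the floor of 82.5 units. Tnni2 lay between 363.8 and 925.7 on the 6 arrays without Hdac2 and was at most 133.7 on the 6 arrays with it.

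Loss of Hdac2 alone was compared with wild type. Besides Hdac2, the one gene called was Tnni2, which encodes the fast skeletal muscle isoform of troponin I. Its signal rose from 52.4 ± 29.2 in wild type to 676.5 ± 244 in Hdac2-null ventricles (n = 3 each), 7.77-fold after the floor (log2 2.96, SE 0.28, adjusted p = 0.00189), and was higher on 3 of 3 arrays. A second Tnni2 probe set measured 33.5 ± 8.13 in wild type and 110 ± 37.9 in Hdac2-null ventricles (adjusted p = 0.844 among all probe sets), and the third was at 4.48 or below in both groups. Transcripts of the contractile and stress programme of the heart did not pass the test. Nppa and Nppb, the natriuretic peptides, measured log2 -0.17 (SE 0.20) and 0.29 (SE 0.17). The myosin heavy chains Myh6 and Myh7 measured -0.04 (SE 0.05) and 0.03 (SE 0.03), and the cardiac transcription factor Gata4 measured 0.04 (SE 0.08). The cell cycle genes Ccnd2 and Cdk4 measured -0.06 (SE 0.08) and 0.07 (SE 0.10), Hdac1 measured 0.08 (SE 0.08), and the phosphoinositide phosphatase Inpp5f measured 0.02 (SE 0.20). Skeletal alpha-actin, Acta1, was at 1035 ± 724 against 1733 ± 928 (adjusted p = 0.925). Hopx was at 12040 ± 317 against 9817 ± 2080 (log2 0.31, SE 0.11, adjusted p = 0.893). Gja5, a gap junction gene, lay between 4.60 and 4.71 on all 12 arrays and was not tested.

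The smallest p among genes that did not pass in Hdac2-null ventricles included that of Ddo, the gene of D-aspartate oxidase, which lies 13 tested genes from Hdac2 on its chromosome (946 ± 216 against 2899 ± 1360, log2 -1.55, SE 0.30, adjusted p = 0.411). Ctsc, the protease cathepsin C, measured log2 -0.51 (SE 0.10), and Ank, a pyrophosphate transporter, measured -0.56 (SE 0.11). Klhl32 was below the floor in every Hdac2-null ventricle, at least 1.49-fold lower (adjusted p = 0.411 for each). In the other direction, Ftcd, a folate-dependent enzyme, measured 0.76 (SE 0.14), and Tdrkh, a tudor domain gene of the piRNA pathway, was at least 1.79-fold higher (adjusted p = 0.411 for both). Sall4, a transcription factor of early embryos, measured 0.77 (SE 0.18, adjusted p = 0.81), and the adhesion molecule Alcam measured 0.30 (SE 0.07, adjusted p = 0.721). In all, 2 of 9667 genes were called, 1 higher and 1 lower. An unadjusted p under 0.05 was reached by 494 genes, where 483 are expected if no gene changed. Genes vary together, and such counts were not set against other splits of the arrays, so here and below they do not measure an effect. Without the floor 4 genes were called and Tnni2 was not among them (log2 3.77, adjusted p = 0.283). Without wild type 3, 4 genes were called, with Hopx (log2 0.48, adjusted p = 0.0339) and Dpep1 (log2 -0.88, adjusted p = 0.04) added.

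Of 33 gene lists, 6 passed at the preset correlation in Hdac2-null against wild type, and 0 with an estimated one. Leukocyte and macrophage markers were lower in 6 of 8 members (median log2 -0.27, adjusted p = 0.00839, and adjusted p = 0.388 with an estimated correlation). Csf1r, the macrophage growth factor receptor, was at 3891 ± 219 against 4595 ± 212, and the signalling adaptors Fcer1g and Tyrobp measured log2 -0.39 (SE 0.15) and -0.28 (SE 0.10). Fibroblast markers were lower in 8 of 8 members (median -0.10, adjusted p = 0.0125, and adjusted p = 0.388 with an estimated correlation), among them the collagen gene Col3a1 (log2 -0.11, SE 0.03) and Pdgfra (-0.11, SE 0.07). Oxidative phosphorylation genes were lower in 22 of 25 members by small amounts (median -0.04, adjusted p = 0.0223, and adjusted p = 0.594 with an estimated correlation), as for Cox5b (-0.05, SE 0.03) and Uqcrc2 (-0.04, SE 0.03). Immediate early and heat shock genes were higher in 11 of 13 members (median 0.10, adjusted p = 0.0223, and adjusted p = 0.46 with an estimated correlation). The stress-induced factor Atf3 measured log2 0.75 (SE 0.24) and Fos 0.58 (SE 0.51). Wnt pathway genes were higher in 11 of 13 members (median 0.16, adjusted p = 0.0442, and adjusted p = 0.388 with an estimated correlation), including Myc at 0.46 (SE 0.24). Liver markers were higher in 3 of 3 members (median 0.44, adjusted p = 0.0223, and adjusted p = 0.388 with an estimated correlation). Alb was at 176 on Hdac2-null 3 and at most 4.59 on the other 11 arrays, Afp was at 205 on Hdac2-null 3 and 33 on Hdac2-null 2, and Ttr was at 188 on Hdac2-null 3, 110 on Hdac2-null 2 and 105 on Hopx-null 1. Interferon response genes (median -0.28, adjusted p = 0.0565) and sarcomere genes (median -0.02, adjusted p = 0.113) did not pass.

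Adjusted over the list alone, Csf1r, Col3a1, Tnni2 and Hbb-y, an embryonic globin of the erythroid and developmental stage lists, were called in Hdac2-null ventricles, and of these Tnni2 alone was called over all genes. Genes named here and below because they were called over a list alone were chosen after their values were seen. The leukocyte list passed without each array in turn (adjusted p at most 0.0343). Fibroblast markers lost their call without wild type 3 or Hdac2-null 2 (adjusted p at most 0.067), and immediate early genes without wild type 2, wild type 3 or Hdac2-null 3 (0.522). Oxidative phosphorylation lost it without wild type 1, wild type 2, Hdac2-null 1 or Hdac2-null 2 (0.538). The Wnt pathway lost it without the floor and without wild type 2, wild type 3, Hdac2-null 1, Hdac2-null 2 or Hopx-null 1 (0.35). Liver markers lost it without wild type 2 or 3 (0.0986), and had too few tested genes without Hdac2-null 3. The oxidative phosphorylation and liver lists also lost it without wild type 1 and Hopx-null 1 together.

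**Figure D2:**
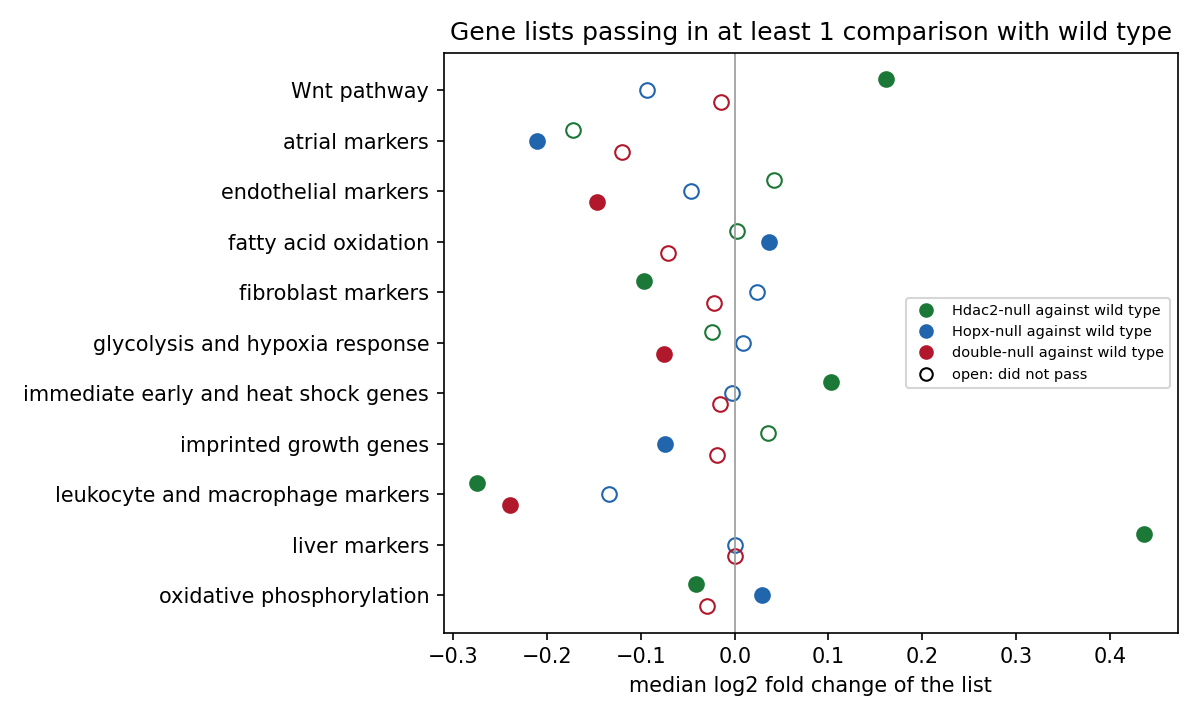
Median log2 fold change (horizontal axis) of each gene list that passed camera at the preset correlation in at least 1 comparison of a null group with wild type; colours are the comparisons, filled points passed and open points did not. Leukocyte and macrophage markers had medians of -0.27 in Hdac2-null, -0.13 in Hopx-null and -0.24 in double-null ventricles, all against the same 3 wild-type arrays.

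For loss of Hopx alone, Hopx itself was the only gene called. Hopx was 4.86-fold lower than in wild type (log2 -2.28, SE 0.11, adjusted p = 5.74e-06). Tnni2 signal was 65.4 ± 59.7 against 52.4 ± 29.2, and Hdac2 measured log2 0.01 (SE 0.11). Among cardiac genes that did not pass, Nppa measured 0.15 (SE 0.20), Nppb 0.07 (SE 0.17), Gata4 -0.01 (SE 0.08), Ccnd2 -0.02 (SE 0.08), Cdk4 -0.04 (SE 0.10) and Inpp5f -0.35 (SE 0.20), each with an adjusted p of 1. Acta1 measured -0.20 (SE 0.58), Hdac1 0.03 (SE 0.08), Myh6 0.03 (SE 0.05) and Myh7 0.01 (SE 0.03). The smallest p among higher genes belonged to Ttc27 (log2 0.94, SE 0.24), Ftcd (0.50, SE 0.14), Rccd1 (0.43, SE 0.11), Zfp708 (0.51, SE 0.15) and Gbe1, the glycogen branching enzyme (0.25, SE 0.07). Among lower genes it belonged, after Hopx, to Klhl32 (at least 1.49-fold), Ccdc184 (-0.56, SE 0.11), Asb18 (-0.63, SE 0.16) and the peptidase gene Dpp4 (-0.57, SE 0.15). Their adjusted p lay between 0.726 and 1. At an unadjusted p under 0.05 there were 256 genes, fewer than the 483 expected if no gene changed. Without the floor 2 genes were called, Hopx and Tbrg3 (log2 -0.56, adjusted p = 0.0158).

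Atrial markers were lower in Hopx-null ventricles in 6 of 8 members (median log2 -0.21, adjusted p = 0.0138, and adjusted p = 0.667 with an estimated correlation). Against the same wild-type arrays they were also lower, without passing, in 8 of 8 members in Hdac2-null (median -0.17, adjusted p = 0.0565) and 7 of 8 in double-null ventricles (median -0.12, adjusted p = 0.251). The atrial myosin light chain Myl4 was at 18480 ± 216 against 21590 ± 2360, and Kcnj3, an atrial potassium channel, measured log2 -0.38 (SE 0.19). Pam measured -0.20 (SE 0.07) and Sln, the calcium pump regulator sarcolipin, -1.35 (SE 0.87). Oxidative phosphorylation genes were higher in 20 of 25 members by small amounts (median 0.03, adjusted p = 0.0139, and adjusted p = 0.886 with an estimated correlation), as for Sdha (0.08, SE 0.04). Fatty acid oxidation genes were higher in 16 of 21 members (median 0.04, adjusted p = 0.0311, and adjusted p = 0.667 with an estimated correlation), including the fatty acid transporter Cd36 (0.10, SE 0.06). Imprinted growth genes were lower in 11 of 11 members (median -0.07, adjusted p = 0.0311, and adjusted p = 0.667 with an estimated correlation), with Grb10 at -0.08 (SE 0.04). Upk3b, a mesothelial marker, was the one gene called when adjusted over the list alone (1195 ± 170.3 against 1664 ± 206.4, log2 -0.48), and no list member was called over all genes. Atrial markers lost their call without wild type 1 or Hopx-null 2 (adjusted p at most 0.374) and without wild type 1 and Hopx-null 1 together. Oxidative phosphorylation lost it without wild type 3 or Hopx-null 2 (0.975), and imprinted genes without wild type 1, wild type 3 or Hopx-null 2 (0.701). Fatty acid oxidation lost it without wild type 2, wild type 3, Hopx-null 2 or Hopx-null 3 (0.287) and without the floor. Both metabolic lists also lost it with quantile normalisation.

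For loss of both genes, Hdac2, Hopx and Tnni2 were called. Hopx was 5.7-fold lower than in wild type (log2 -2.51, SE 0.11, adjusted p = 1.04e-06). Tnni2 rose to 488 ± 108, 5.76-fold after the floor (log2 2.53, SE 0.28, adjusted p = 0.00598), on 3 of 3 arrays. The smallest p among genes that did not pass included those of Myef2, a repressor first described on the myelin basic protein gene (8184 ± 413 in wild type and 10340 ± 488 in double-null ventricles, n = 3 each, log2 0.34, SE 0.06, adjusted p = 0.219), and the imprinted gene Peg12 (log2 0.64, adjusted p = 0.236). A second Myef2 probe set went from 828.2 ± 94 to 1389 ± 23.9 and passed in a test of all probe sets (log2 0.75, adjusted p = 0.0303), and the third did not (log2 0.44, adjusted p = 0.689). With array weights Myef2 was called (log2 0.37, SE 0.05, adjusted p = 0.0316). Tdrkh was at least 1.83-fold higher (adjusted p = 0.421), and Meioc, a meiosis gene, measured 1.27 (SE 0.26, adjusted p = 0.501). Ctsc (-0.48, SE 0.10), Antxr2, an anthrax toxin receptor (-0.41, SE 0.09), and Klhl32 (-0.50, SE 0.10) each had an adjusted p of 0.501. Acta1 was at 742 ± 203 against 1733 ± 928 (adjusted p = 0.69). Hdac1 measured log2 0.15 (SE 0.08), Nppa -0.17 (SE 0.20), Nppb 0.14 (SE 0.17), Gata4 0.01 (SE 0.08) and Ccnd2 -0.11 (SE 0.08). Cdk4 measured -0.10 (SE 0.10), Inpp5f 0.12 (SE 0.20), Myh6 0.05 (SE 0.05) and Myh7 0.01 (SE 0.03). In all 3 of 9667 genes were called, and 707 had an unadjusted p under 0.05. The Tnni2 call ended without the floor (log2 3.34, adjusted p = 0.319) and without wild type 1 (2.52, adjusted p = 0.0514), double-null 2 (2.43, adjusted p = 0.0546) or double-null 3 (2.43, adjusted p = 0.0547). Without wild type 3, 8 genes were called.

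Endothelial markers were lower in double-null ventricles in 17 of 20 members (median log2 -0.15, adjusted p = 0.0309, and adjusted p = 0.552 with an estimated correlation), among them Pecam1 (264 ± 39.2 against 369 ± 77.1) and the VEGF receptor Kdr (log2 -0.30, SE 0.15). Glycolysis and hypoxia response genes were lower in 16 of 21 members (median -0.08, adjusted p = 0.0309, and adjusted p = 0.893 with an estimated correlation). The lactate transporter Slc16a3 measured -0.58 (SE 0.20), Ankrd37 -0.48 (SE 0.15) and the phosphofructokinases Pfkm and Pfkl -0.20 (SE 0.08) and -0.27 (SE 0.12). Leukocyte markers were lower in 7 of 8 members (median -0.24, adjusted p = 0.0309, and adjusted p = 0.552 with an estimated correlation), with Csf1r at 3808 ± 252 against 4595 ± 212. Genes of the G1/S phase and DNA replication (median 0.06, 17 of 27 higher) and of the sarcomere (median -0.03, 18 of 26 lower) did not pass (adjusted p = 0.0544 for both). Nor did those of G2/M (adjusted p = 0.355), cardiac transcription factors (0.647) or GATA4 targets (0.93). Adjusted over the list alone, Csf1r, Tcap, a sarcomeric Z-disc gene, and Myl1 and Tnni2 of the skeletal muscle list were called, and of these Tnni2 alone was called over all genes. All 3 lists lost their call without wild type 1, wild type 2, double-null 1 or double-null 3 (adjusted p at most 0.161), and without wild type 1 and Hopx-null 1 together. With the replicate number as a block 2 of the 3 lists passed, and the leukocyte list did not.

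Where Hdac2 was absent, Hopx was the only gene called for additional loss of Hopx. It was at 1700 ± 38.6 in double-null against 12040 ± 317 in Hdac2-null ventricles, 7.08-fold lower (log2 -2.83, SE 0.11, adjusted p = 5.92e-07). There were 1097 genes with an unadjusted p under 0.05, 624 of them higher, against 483 expected if no gene changed. Gene lists were tested in this comparison only after the results were seen. Endothelial markers were lower in 17 of 20 members (median log2 -0.19, adjusted p = 0.0139, and adjusted p = 0.589 with an estimated correlation). Genes of the G1/S phase and DNA replication were higher in 22 of 27 (median 0.13, adjusted p = 0.0155, and adjusted p = 0.833 with an estimated correlation). With array weights, which ran from 0.31 for wild type 1 to 7.98 for double-null 2, 951 genes were called, 556 higher and 395 lower. The weights of double-null 1 and 3 were 1.43 and 0.818. Those of Hdac2-null 1, 2 and 3 were 3.05, 0.769 and 0.875. In each group 1 array thus carried most of the weight, and the 951 calls rest largely on double-null 2 and Hdac2-null 1.

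Where Hopx was absent, Hdac2 and Tnni2 were the genes called for additional loss of Hdac2. Hdac2 was at least 59.1-fold lower (adjusted p = 9.83e-11). Tnni2 went from 65.4 ± 59.7 in Hopx-null to 488 ± 108 in double-null ventricles (4.95-fold after the floor, log2 2.31, SE 0.28, adjusted p = 0.0215), higher on 3 of 3 arrays. None of these 6 arrays entered the fold change between Hdac2-null and wild type, although all 12 arrays shared 1 estimate of the spread. There were 786 genes with an unadjusted p under 0.05. Gene lists were tested in this comparison only after the results were seen. At camera's preset correlation, lower lists that passed were oxidative phosphorylation (21 of 25 members, adjusted p = 0.000978), fatty acid oxidation (15 of 21, adjusted p = 0.00951) and sarcomere (17 of 26, adjusted p = 0.0458). With an estimated correlation their adjusted p was 0.949, 0.842 and 0.842. The Tnni2 call ended without the floor (log2 3.27, adjusted p = 0.507), with the replicate number as a block (adjusted p = 0.097) and with only the groups compared. It also ended without wild type 1 (0.0632), wild type 2 (0.0603), Hdac2-null 2 (0.0598), Hopx-null 2 (0.186), Hopx-null 3 (0.133), double-null 2 (0.184) or double-null 3 (0.123). In these fits without an array and with the replicate block the log2 fold change stayed between 2.19 and 2.31.

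The interaction of the 2 losses is the effect of Hdac2 loss without Hopx minus that with it. Fatty acid oxidation genes were lower in 15 of 21 members (median log2 -0.07, adjusted p = 0.0285, and adjusted p = 0.607 with an estimated correlation). The members with the smallest p were Hadha, a subunit of the mitochondrial trifunctional protein (-0.45, SE 0.15), Fabp3, a fatty acid binding protein (-0.12, SE 0.04), Cd36 (-0.21, SE 0.09) and Decr1 (-0.34, SE 0.19). Adjusted over the list alone, Hbb-y (log2 -3.55, SE 0.97) and Emcn, an endothelial sialomucin (-0.57, SE 0.13), were called. Over all genes limma called 0, with 404 at an unadjusted p under 0.05 and 483 expected if no gene changed. Without wild type 3 it called 1, Hopx (log2 -0.71, adjusted p = 0.0449). The fatty acid oxidation list lost its call with median centring and without wild type 2, wild type 3, Hdac2-null 1, Hopx-null 3 or double-null 3 (adjusted p at most 0.111). The median SE of the interaction was 0.16 on the log2 scale, and small departures from additivity were not detectable gene by gene with 3 ventricles per group.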

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

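All tests in this part other than the interaction itself, which was fixed before the data were examined, had their criteria written after the results were seen. The interaction for fatty acid oxidation genes was picked out because a test of the difference between the effects of Hdac2 loss with and without Hopx passed at the preset correlation (adjusted p = 0.0285, and adjusted p = 0.607 with an estimated correlation). Against wild type, the median log2 fold change of these genes was 0.04 in Hopx-null, 0.00 in Hdac2-null and -0.07 in double-null ventricles. Chance was not excluded for the number of lists: the real grouping passed 1 list, 92 of 100 drawn groupings of the 12 arrays passed as many, and the highest other passed 12. For genes the real grouping called 0, so all 100 drawn groupings called as many. The highest other called 37, the next highest called 6, and 92 called 0. The grouping with 37 calls set wild type 2 and 3, the 3 Hdac2-null arrays and Hopx-null 2 against the other 6 arrays. The same division gave the highest count for Hopx loss averaged over Hdac2 status, 164 genes. This division is the real Hopx grouping with only wild type 1 and Hopx-null 2 exchanged, and it parts Hdac2-null from double-null ventricles. An effect of Hopx loss alone would be expected to call most genes under the real Hopx grouping, which called 0 besides the targeted genes. The 164 calls therefore argue for another structure of the arrays, with or without an effect of Hopx loss. The source of that structure was not tested.

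Tnni2 was the one gene besides the targets to be called in the main fit, and it was called in each comparison that isolates Hdac2 loss. Skeletal muscle tissue in the dissected ventricles would bring its other fast fibre transcripts, but the 11 genes of the skeletal list that ventricle lacked, Mylpf, Tnnt3 and Tnnc2 among them, reached at most 6.09 units on the 6 arrays without Hdac2, far below the floor (the other 3, Tnnt1, Myl1 and Ckm, are also expressed in wild-type ventricle). The sex of the embryos was argued against too, as with log2 Xist as a covariate the log2 fold change averaged over Hopx status was 2.60 (SE 0.20), next to 2.63 (SE 0.19) without it. The floor was not the source of the difference, as before it the 6 arrays without Hdac2 were at 363.8 or more and the 6 with it at 133.7 or less, but the calls depended on it in part: without it the averaged value of 3.52 (SE 0.43) passed narrowly (adjusted p = 0.046), and the 3 single comparisons lost their calls (log2 3.77, 3.34 and 3.27, adjusted p = 0.283, 0.319 and 0.507), as low signals then added spread, with an SE of 0.61 against 0.28. A direct or indirect repression of Tnni2 by Hdac2 stays open, as do other effects of the targeted allele, and neither was tested.

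Genes beside Hdac2 on its chromosome differed with Hdac2 loss more often than those in most other places. Of its 40 nearest tested neighbours, 11 had an unadjusted p under 0.05 for Hdac2 loss averaged over Hopx status, 6 higher and 5 lower. They were led by Ddo (log2 -1.22, SE 0.21) and Hint3 (-0.38, SE 0.09). Of the other windows, which overlap one another, 0.137% held as many. That argues against placement by chance only as far as a test set up after the results were seen can. Of 100 drawn groupings within Hopx status, 1 gave as many as 11, the real one, and the highest other gave 8. As the count includes Ddo and its criterion was written after the results were seen, this share does not exclude chance. Array differences that follow Hdac2 status, such as shared litters or days, were not tested. Of the neighbours of Hopx, 8 of 40 differed for Hopx loss, with 2.69% of other windows holding as many. Of 100 groupings within Hdac2 status, 2 gave as many, a share under 0.05. The other of these, the grouping with 164 calls, gave 10. It only exchanges wild type 1 and Hopx-null 2, so a real difference beside Hopx could contribute to its count. Such a difference alone would be expected to give its highest count under the real labels, which gave 8. The share of 2 in 100 therefore excludes neither chance nor a structure of the arrays. Both the groupings and the p-values ignored the possible pairing by replicate number. Of the 8 genes, 3 also differed for Hdac2 loss, which leaves the structure of the arrays open for them in particular. A chromosome segment of another strain carried along with each targeted allele may account for such genes, as may a local effect of the allele; neither was tested, and none of the neighbours passed over all genes (adjusted p = 0.131 for Ddo).

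Leukocyte and macrophage markers were lower in Hdac2-null and double-null ventricles against the same wild-type arrays at the preset correlation (adjusted p = 0.388 and adjusted p = 0.552 with an estimated correlation). The list was also lower in Hopx-null ventricles against these arrays, in 6 of 8 members, without passing (median -0.13, adjusted p = 0.0635). Between double-null and Hopx-null ventricles, which use no wild-type array, the list's median was -0.0973 and camera did not pass it (adjusted p = 0.54), so high values on the wild-type arrays alone and an effect of Hdac2 loss cannot be told apart with this number of arrays. A smaller share of leukocytes also stays open: the highest lower bound of the intervals of 7 members over 4 floors, corrected for taking the highest of 7, was -0.331, below the list's median of -0.179. A first version of that test, with uncorrected 95% intervals, had come out against a smaller share, with a bound of -0.172 for Lyz1 (log2 0.18, SE 0.16), and was replaced after this result was seen because it took the most extreme of 7 members.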

How the results depend on the processing

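The Xist covariate, the filter at 2 floors and the fit without wild type 1 and Hopx-null 1 were chosen after the data were seen; all other alternatives were fixed before the data were examined. No result reversed. Counts of called genes stayed within 1.5 times their value under quantile normalisation, median centring, no intensity trend, without sex-linked genes, with the Xist covariate and at 2 floors in all 6 comparisons. Leaving out the filter tested nothing, since the same number of genes, 9667, was left. The cause of the changes below was not tested except where stated. Without the floor, Hdac2-null against wild type called 4 genes (Tnni2 lost; Tbrg3, Adgre1 and Pstpip2 added, all lower), Hopx-null against wild type 2 and double-null against Hopx-null 1, among 12433 genes tested. With all probe sets as features the counts were 2 for Hopx-null, 6 for double-null against wild type and 2 for double-null against Hdac2-null, since 2 probe sets of each deleted gene then count, and in double-null against wild type a Myef2 probe set was added (log2 0.75). Array weights, under which double-null 2 carried most of the weight of its group (7.98), called 951 genes in double-null against Hdac2-null. They added Myef2 in double-null against wild type (4 genes). For double-null against Hopx-null, only the groups compared gave 1 gene, and leaving out wild type 1 and Hopx-null 1 gave 5. The replicate block gave 1 gene in double-null against Hopx-null, ended the leukocyte list in double-null against wild type, passed 7 lists in place of 6 in Hdac2-null, and changed no other call.

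Leaving out 1 array at a time gave 2 to 4 genes in Hdac2-null, 1 to 1 in Hopx-null and 2 to 8 in double-null against wild type, 1 to 1 in double-null against Hdac2-null, 1 to 3 in double-null against Hopx-null and 0 to 1 in the interaction. The highest counts in Hdac2-null (4), double-null (8) and the interaction (1, Hopx) came without wild type 3, whose Hopx signal of 12220 lay above 8653 and 8577 on the other wild-type arrays. A group left with 2 arrays shared the spread of the others.

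For gene lists, an estimated correlation and fry each passed 0 in all 4 comparisons, where camera at the preset correlation passed 6, 4, 3 and 1. Hopx-null passed 2 with quantile normalisation, double-null 5 with the Xist covariate, and the interaction 3 without the floor, 0 with median centring and 4 without the 2 arrays. Without single arrays the lists passing were 2 to 7 in Hdac2-null, 0 to 8 in Hopx-null, 0 to 5 in double-null and 0 to 9 in the interaction. For the 120 named gene results, a called value was counted as kept where its direction and call stayed, whatever its size. A value not called was counted as kept where its log2 fold change stayed within a margin set from its SE, whatever its adjusted p. By these rules 1882 of 1917 refitted values were kept, 21 moved and 14 lost their call. Calls gained were not counted, such as Tdrkh in double-null against wild type without Hdac2-null 2 (log2 0.87, adjusted p = 0.0232). Signal over background limits the result: 60.2% of probe sets were at the floor on all arrays.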

Other observations

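All tests and genes in this part were chosen after the results were seen. Averaged over Hopx status, 6 arrays against 6, loss of Hdac2 called Hdac2 and Tnni2 (log2 2.63, adjusted p = 0.000182), and 866 genes had an unadjusted p under 0.05. Higher without passing were Tdrkh of the piRNA pathway (152 ± 29.1 against 71.1 ± 14.4, n = 6 each, adjusted p = 0.0699), the meiosis gene Meioc (249.9 ± 65.9 against 111 ± 24.3, adjusted p = 0.1) and Sall4 (849 ± 88.3 against 504 ± 97.6, adjusted p = 0.1). Lower without passing were Ctsc (452 ± 27.9 against 624 ± 31.7, adjusted p = 0.0737), Paqr9 (118 ± 40 against 373 ± 115, adjusted p = 0.1) and the caveolar muscle gene Cavin4 (980.4 ± 115 against 1617 ± 332, adjusted p = 0.182). Oxidative phosphorylation genes were lower in 23 of 25 members (median log2 -0.05, adjusted p = 6.49e-05, and adjusted p = 0.634 with an estimated correlation). Sarcomere genes were lower in 20 of 26 members by small amounts (median -0.03, adjusted p = 0.0221, and adjusted p = 0.634 with an estimated correlation). Leukocyte and macrophage markers were lower in 6 of 8 members (median -0.18, adjusted p = 0.0301, and adjusted p = 0.634 with an estimated correlation).

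Averaged over Hdac2 status, loss of Hopx called Hopx alone (log2 -2.55), with 844 genes at an unadjusted p under 0.05. Endothelial markers were lower in 16 of 20 members (median log2 -0.09, adjusted p = 0.0399, and adjusted p = 0.639 with an estimated correlation). Genes of the G1/S phase and DNA replication were higher in 22 of 27 members (median 0.06, adjusted p = 0.0466, and adjusted p = 0.722 with an estimated correlation). Neither list passed in Hopx-null against wild type (medians -0.05 and 0.03, adjusted p = 0.649 for each). Both passed at the preset correlation in double-null against Hdac2-null (medians -0.19 and 0.13).

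The counts were set against other splits of the same arrays. For the averaged effects both targeted genes were left out, since their deletion fixes their calls in the real grouping. For Hdac2 loss averaged over Hopx status, the real grouping then called 1 gene, Tnni2, the highest of the others called 1, and 5 of 100 drawn groupings called as many, so chance was not excluded for the count. For Hopx loss averaged over Hdac2 status the real grouping called 0, so all 100 called as many. The highest other called 164, and differs from the real one only in the exchange of wild type 1 and Hopx-null 2. The counts for pairs of groups include the targeted genes. Pairs of groups of 3 give 10 splits, too few for a share under 0.05. For Hdac2-null against wild type the real split called 2 genes and the highest other 4 (2 of 10 as many), and passed 6 lists against 8 (2 of 10). For Hopx-null against wild type the values were 1 gene against 1 (2 of 10) and 4 lists against 7 (4 of 10). For double-null against wild type they were 3 genes against 1 (1 of 10) and 3 lists against 8 (4 of 10). Double-null against Hdac2-null gave 1 gene against 1 (3 of 10), and double-null against Hopx-null 2 genes against 0 (1 of 10).

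Fold changes of Hdac2 loss measured with and without Hopx, on arrays that are not shared, correlated across 9658 genes without the targets and sex-linked genes (Pearson r 0.309, Spearman rho 0.191; genes are not independent replicates). Of 200 relabellings within Hopx status, a share of 0.055 gave as high a correlation (1-sided exact permutation p, adjusted p = 0.11 over 2 tests). For Hopx loss with and without Hdac2, r was 0.208, rho 0.166 and the exact permutation p was 0.17 (adjusted p = 0.17). Array structure without an effect of either gene could give correlations of this size.

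Hbb-y, an embryonic globin, varied widely within groups. Its signals were 1209, 985 and 219 in Hdac2-null ventricles and 7.66, 4.85 and 123 in wild type (log2 2.76, SE 0.69, adjusted p = 0.892). They were 427, 4.89 and 5.70 in Hopx-null and 47.4, 16.2 and 64.7 in double-null ventricles.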
